A study of Homo sapiens with 42 samples.

How the data were processed

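Whole-genome expression was measured on Illumina bead arrays in 1205Lu cells, a human melanoma cell line derived from a metastasis, after treatment with 1 of 2 Aurora kinase inhibitors. AZD1152 was given at 0.5 µM and SNS-314 at 0.05 µM, and cells were collected after 6, 12, 18, 24 and 48 h; untreated cells at 0 h served as the control. Per the labels, cells were grown in Tu2% medium to 70% confluency, total RNA was extracted with TRI Reagent, and an Ambion MessageAmp kit was used to make biotin-labelled cRNA. The 42 arrays fall into 11 groups, with 4 arrays in the control group, 3 in each group at 6 h and 4 in each later group. The labels number the replicates within each group and do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No untreated cells were measured at 6 h or later in the data used here, so every change against the control includes whatever the time in culture did.

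The authors deposited a table of probe intensities on a linear scale, without background subtraction or normalization as far as the values show, with 1 column per array and no detection p-values or control probes in the table used here. They also deposited processed values on a log2 scale. In these every array has the same set of values, as after quantile normalization; the authors' background correction, scale and centring are not given in the sources used here. Each of the 42 columns of processed values correlated best with the intensities of its own array, and these values were used as an alternative. The scanner software is not given in the sources used here.

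The table holds 47312 probes. A gene was named from the platform annotation for probes with exactly 1 listed symbol, which were 30110 probes; 8 probes list several symbols and 17194 list none and are unnamed here. Entrez identifiers matched a current gene record for 30071 of the named probes, and 0 symbols needed an update. Because negative control probes were not used here, 437 probes for olfactory receptor genes, which are silent in most cells outside the nose, stood in for them. The median intensity per array ran from 210 to 338.6, and the median of the olfactory receptor probes from 167.7 to 270.1, so a typical probe lay close to background. Background was corrected with the normexp model fitted on the stand-in probes with an offset of 16 (nec), and arrays were quantile-normalized on the log2 scale. A probe was called detected on an array when fewer than 1 in 100 of the stand-in probes were as bright (detection p of 0.01), and the 18823 probes detected on at least 3 arrays were tested. Of these, 14485 have 1 symbol and represent 11074 genes. The highest correlation between any pair of arrays was 0.993 and 0 pairs were identical.

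Changes were tested with limma (version 3.58.1, R 4.3.3), using 1 model with a mean per group over all 42 arrays, moderated variances (lmFit, contrasts.fit, eBayes) and Benjamini-Hochberg adjustment over the tested probes of each comparison. A probe was called changed at an adjusted p under 0.05. Errors of log2 changes are standard errors (SE) and errors of group levels are standard deviations (SD); intervals are 95% confidence intervals. Each drug was compared with the control at each time, the drugs with each other at each time, 48 h with 6 h within each drug, and the change from 6 to 48 h between the drugs (the drug-by-time contrast). The number of arrays limits the precision of every value. Where a probe was undetected on every array of 1 group, only a bound is given. It sets the bright group's mean against the mean, per array, of the higher of the lowest detected signal and the probe's own signal, and is written as "at least N-fold".

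Gene lists were fixed from general knowledge: the chromosomal passenger complex and Aurora kinases, mitotic genes, DNA replication genes, histone genes, p53 target genes, CDK inhibitors and the Rb family, senescence-associated secretory genes, NF-kB target genes, interferon response genes, antigen presentation genes, melanocyte lineage genes, neural crest and invasive melanoma genes, lysosome and autophagy genes, ER stress and integrated stress response genes, heat shock genes, cholesterol biosynthesis genes, hypoxia and glycolysis genes, extracellular matrix genes, YAP target genes, immediate-early and MAPK output genes, BCL2 family genes, nuclear lamina and chromatin genes, ribosomal protein genes, cytoskeleton genes, and markers of keratinocytes, of immune cells, and of endothelial cells and fibroblasts. A list was tested with camera against all other genes, with 1 probe per gene (the one with the highest mean), a preset correlation of 0.01 and adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it.

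Genes named in the text were chosen by a rule among probes with 1 symbol, past the threshold and moved the same way in every treated array. The rule takes the 10 largest rises and 10 largest falls for each drug at 48 h and 3 each way at earlier times, 5 each way for the drugs against each other at 48 h and 3 at other times, 5 each way for 48 h against 6 h and for the drug-by-time contrast, and up to 4 members per list. Whatever their values, AURKA, AURKB, AURKC, INCENP, BIRC5, CDKN1A, CDKN2A, MDM2, CCNB1, MKI67, TOP2A, LMNB1, GLB1, IL6, CXCL8, CCL2 and MITF were also named; 1 further gene of the rule is not reported here. AURKC and CDKN2A have 3 probes each, which were detected on 0 arrays, so no change is given. The sample groups, tests, gene lists, naming rule and most alternatives were chosen before the data were examined; alternatives added later are named where their effect is given. The unit of the table and the missing detection values became known only with the data, so the olfactory receptor probes were chosen then.

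The column names of the intensity table end in a letter and 2 digits, which were read here as the position and the slide of each array. The labels state no slide or batch. Read this way, the arrays lie on 4 slides. Slides 1, 2 and 3 hold 12 arrays each and slide 4 holds 6; the controls lie on slides 1 and 2, with 2 arrays each. The slide was entered as a block, and each comparison was also made within every slide that holds both groups. On slides 1 and 2 the controls take the first positions and the times follow in order. An effect of the position on the slide therefore cannot be told apart from treatment or time, within slides too. A pairing of samples by replicate number was checked from the correlation of deviations from the group means. Between the drugs, every same-numbered pair correlated above 0.1 at 6 h (0.15 to 0.24), 12 h (0.14 to 0.31) and 24 h (0.25 to 0.39), and so did 48 h with 6 h for AZD1152 (0.16 to 0.19) and SNS-314 (0.13 to 0.22); the pairing comes from the replicate numbers in the labels, which largely follow the slides.

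Alternatives were no background correction, normexp without negative controls and with an offset of 50, median centring in place of quantile normalization over all or over detected probes, no detection filter, a looser one (detection p of 0.05) and detection on all 42 arrays, the authors' processed values, eBayes with a trend and robust variances, array weights, the slide or the replicate number as a block, only the arrays of the groups compared, only slides 1 and 2, leaving out 3 arrays picked by eye from the principal components, and leaving out each replicate in turn. The tests were run on simulated data made from each probe's mean over all 42 arrays and its spread within groups. The simulated noise was normal and independent between arrays and probes, so differences between slides do not enter these shares. In each simulated comparison 67 probes were changed 1.5-fold, 67 2-fold and 66 4-fold, on values already normalized. With the real data 5407 probes were called for AZD1152 at 48 h, so the shares may not hold where so many probes change. For AZD1152 at 48 h against control, 97.0% of probes changed 2-fold and 50.7% of those changed 1.5-fold were recovered, with 5 unchanged probes called among 18823. For AZD1152 at 6 h the shares were 92.5% and 59.7% with 9 unchanged probes called, and for AZD1152 against SNS-314 at 48 h they were 89.6% and 59.7% with 8. In the drug-by-time contrast 58.2% of 2-fold and 13.4% of 1.5-fold changes were recovered. Of lists simulated for AZD1152 at 48 h, the 1 shifted list passed and 0 of the 26 others did. The members of a list were drawn independently, so this does not show how the list test behaves where members move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.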

Results

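Gene expression was measured on 42 Illumina arrays in 1205Lu melanoma cells treated with AZD1152 or SNS-314 and in untreated control cells at 0 h. Aurora kinases drive chromosome segregation and cytokinesis. The series title links the inhibition of these kinases to senescence, a lasting arrest of cell division, so the comparisons follow genes of cell division, of growth arrest and of the secretions that accompany senescence over time. There were 4 control arrays, 3 arrays for each drug at 6 h and 4 for each drug at 12, 18, 24 and 48 h. The doses differed, at 0.5 µM for AZD1152 and 0.05 µM for SNS-314, so values for the drugs stand side by side and do not compare their potency.

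The number of changed probes was highest at 48 h under both drugs. With AZD1152, limma called 288 of the 18823 tested probes at 6 h, 421 at 12 h, 2049 at 18 h, 1972 at 24 h and 5407 at 48 h. With SNS-314 it called 415, 549, 1042, 2279 and 5981. Of these, 64, 44, 123, 134 and 762 moved at least 2-fold with AZD1152, and 79, 47, 73, 170 and 828 with SNS-314. With the slide as a block the counts were 420, 528, 2738, 2417 and 5917 for AZD1152 and 598, 846, 1330, 2660 and 6488 for SNS-314. The first principal component of the tested probes held 29.7% of the variance. Group membership accounted for 51.9% of the variance and the slide, after the groups, for a further 13.9%.

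**Figure D1:**
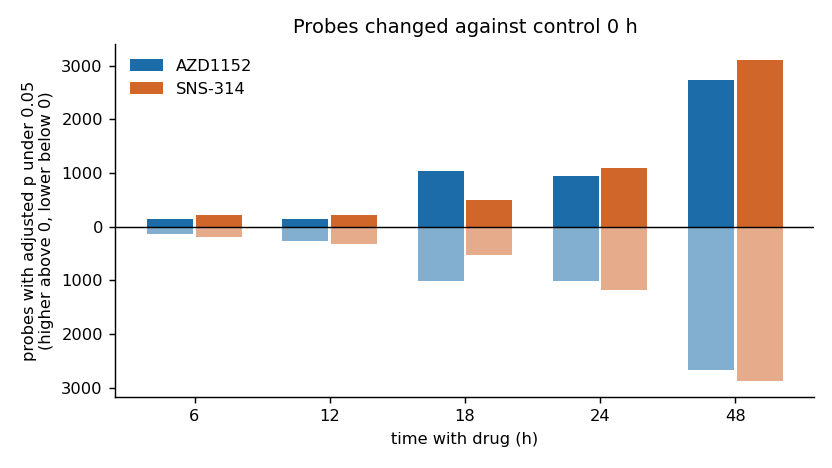
Number of probes called higher and lower than in the control at each time in h, for AZD1152 and SNS-314, at an adjusted p under 0.05 among 18823 tested probes. The bars are tallest at 48 h, with 2739 probes higher and 2668 lower for AZD1152 and 3107 and 2874 for SNS-314.

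At 6 h, the genes with the deepest falls under both drugs encode inflammatory mediators and their regulators. CCL2, which encodes a chemokine that attracts monocytes, fell from 13.96 ± 0.05 (SD, n = 4) in the control to 10.44 ± 0.50 with AZD1152 and 10.40 ± 0.11 with SNS-314 (n = 3 each). On the log2 scale it fell by 3.52 ± 0.18 and fell by 3.55 ± 0.18 (SE; adjusted p = 3.9e-17 and 2.9e-17). CXCL1, another chemokine gene, fell by 3.42 ± 0.47 and by 3.19 ± 0.47. ZC3H12A, which encodes an RNase that degrades cytokine mRNAs, fell by 2.49 ± 0.20 and by 2.57 ± 0.20. CXCL8, the gene for the neutrophil-attracting chemokine IL-8, fell by 2.19 ± 0.20 and by 2.32 ± 0.20, and IL6 fell by 1.75 ± 0.15 and by 1.71 ± 0.15. The largest rises with AZD1152 were in NNMT, a nicotinamide methyltransferase gene (1.53 ± 0.30), the actin-binding gene TAGLN (1.45 ± 0.20) and the immune checkpoint gene VSIR (at least 1.71-fold). With SNS-314 they were in VSIR (at least 2.04-fold), TAGLN (1.65 ± 0.20) and DDAH1 (1.48 ± 0.15), which encodes an enzyme that breaks down methylated arginine.

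Of the 19 measured NF-kB target genes, 15 fell and 0 rose with each drug at 6 h, a time at which no untreated cells were measured; adjusted over the list alone, 17 fell with AZD1152 and 16 with SNS-314. The list's median change was −0.97 and −0.93 (camera, adjusted p = 1.13e-47 and 7.42e-40), with members such as TNFAIP3, an inhibitor of NF-kB signalling (−2.01 and −2.43), and the adhesion gene ICAM1 (−1.77 and −2.05). With the slide as a block the medians were −0.94 and −0.93; within slides 1 and 2 they were −0.91 and −1.10 for AZD1152 and −1.08 and −0.83 for SNS-314. Among 31 senescence-associated secretory genes, 9 fell with AZD1152 and 10 with SNS-314 (11 and 12 adjusted over the list alone), with medians of −0.21 and −0.25 (adjusted p = 2.55e-16 and 6.29e-19), −0.20 and −0.18 with the slide as a block. Interferon response genes fell as a list of 29, with 3 members called for AZD1152 and 7 for SNS-314 (7 and 14 adjusted over the list alone). Among them were the RNA sensor gene IFIH1 (−1.20 and −1.58) and the antiviral gene MX1 (−0.74 and −0.68, the latter call ending without SNS-314 replicate 1, at −0.56). With median centring the MX1 calls (−0.56 and −0.57) and the IFIH1 call of AZD1152 (−0.99) ended, with the direction kept. The list's median was −0.24 and −0.36 (adjusted p = 3.39e-07 and 6.86e-12), −0.23 and −0.39 with the slide as a block, and −0.10 and −0.31 within slides 1 and 2 for AZD1152 and −0.36 and −0.44 for SNS-314.

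Limma called 0 of 47 mitotic, 0 of 46 DNA replication and 0 of 9 passenger complex and Aurora kinase genes at 6 h with either drug. At an unadjusted p under 0.05 there were 2, 2 and 0 for AZD1152 and 2, 1 and 1 for SNS-314. The medians were 0.07, 0.06 and 0.15 (adjusted p = 0.195, 0.22 and 0.0668) for AZD1152 and 0.04, 0.01 and 0.08 (adjusted p = 0.846, 0.922 and 0.468) for SNS-314. Log2 changes of AURKA, AURKB, INCENP, BIRC5, CCNB1, MKI67, TOP2A and LMNB1, and of CDKN1A, MDM2 and GLB1, lay between −0.30 and 0.58 over both drugs. The 27 p53 target genes rose as a list with AZD1152 (median 0.16, adjusted p = 0.0335), with 1 member up and 1 down (3 and 1 adjusted over the list alone), a call lost with the slide as a block (adjusted p = 0.0706). With SNS-314 the median was 0.16. The cholesterol list (median 0.16 and 0.18, adjusted p = 0.0146 and 0.00585) lost its call under both drugs (adjusted p = 0.117 and 0.0726 with an estimated correlation). So did the cytoskeleton list with AZD1152 (median 0.12, adjusted p = 0.00805, against 0.0604 with an estimated correlation) and the antigen presentation list with SNS-314 (median −0.16, adjusted p = 0.0139, against 0.0583 with an estimated correlation).

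At 12 h, the chemokine genes stayed low, and mitotic and DNA replication genes moved in opposite directions. CCL2 fell by 2.84 ± 0.17 with AZD1152 and by 2.69 ± 0.17 with SNS-314, and CXCL1 by 2.94 ± 0.44 and by 3.29 ± 0.44. IL6 fell by 2.39 ± 0.14 and by 2.45 ± 0.14, and CXCL8 by 2.14 ± 0.18 and by 2.18 ± 0.18 (n = 4 each). ICAM1 fell by 2.24 ± 0.19 and by 2.50 ± 0.19. The largest rises were in LYPD1 (1.48 ± 0.21 and 1.31 ± 0.21), TENT5C, which encodes a poly(A) polymerase (1.26 ± 0.11 and 1.20 ± 0.11), TAGLN with AZD1152 (1.34 ± 0.19) and the natriuretic peptide gene NPPC with SNS-314 (1.36 ± 0.19).

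The 47 mitotic genes rose as a list at 12 h, with medians of 0.26 for AZD1152 and 0.22 for SNS-314 (adjusted p = 1.07e-09 and 6.89e-08). Single members reached the threshold in 5 and 4 cases and none fell; adjusted over the list alone 7 rose with AZD1152, and 9 rose and 1 fell with SNS-314. The mitotic kinesin gene KIF20A rose by 0.56 ± 0.12 and 0.60 ± 0.12. The slide block gave medians of 0.28 and 0.21, and slides 1 and 2 gave 0.21 and 0.25 for AZD1152 and 0.19 and 0.07 for SNS-314. The 9 genes of the chromosomal passenger complex and Aurora kinases, which include the kinases that the drugs inhibit, also rose as a list (median 0.26 and 0.31, adjusted p = 0.00419 and 0.000313), with 0 and 1 members called (0 and 3 adjusted over the list alone). Slides 1 and 2 gave 0.17 and 0.28 for AZD1152 and 0.28 and 0.32 for SNS-314. In the same cells, 6 of 46 DNA replication genes fell with AZD1152 and 14 with SNS-314 (20 and 23 adjusted over the list alone). The medians were −0.26 and −0.32 (adjusted p = 4.75e-10 and 3.1e-12), −0.21 and −0.28 with the slide as a block. CHAF1A, which encodes a chromatin assembly factor of the replication fork, fell by 0.82 ± 0.15 and by 1.01 ± 0.15, and E2F2, a transcription factor gene of the entry into S phase, fell by 0.70 ± 0.13 and by 0.93 ± 0.13. With median centring the calls of KIF20A (0.73 and 0.79, larger than before), CHAF1A (−0.64 and −0.72) and E2F2 (−0.54 and −0.69) ended under both drugs. In all, 11 of 37 calls of named genes for AZD1152 and 12 of 39 for SNS-314 were kept, while the mitotic, passenger complex and replication lists passed.

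The p53 target list rose at 12 h (median 0.28 and 0.36, adjusted p = 1.04e-05 and 1.27e-07). Among its members 2 genes were up and 1 down for AZD1152 and 7 up for SNS-314 (8 up and 2 down, and 14 up and 1 down, adjusted over the list alone). Its medians were 0.29 and 0.28 with the slide as a block. GDF15, which encodes a stress-induced cytokine, rose by 0.88 ± 0.17 and 0.72 ± 0.17, the latter call ending without SNS-314 replicate 1 (0.61) or 2 (0.57). CDKN1A, the gene for the CDK inhibitor p21, rose with SNS-314 by 0.36 ± 0.10 (adjusted p = 0.04) and LMNB1, the lamin B1 gene, by 0.70 ± 0.19 (adjusted p = 0.026). The CDKN1A call ended without SNS-314 replicate 3 or 4 (0.33 and 0.29) or control replicate 1, 2 or 3 (0.34, 0.37 and 0.30). The LMNB1 call ended without SNS-314 replicate 3 or 4 (0.67 and 0.49) or control replicate 3 or 4 (0.59 and 0.67). Both calls also ended with median centring, where the rises were larger (0.51 and 0.94). With AZD1152, CDKN1A was 0.29 ± 0.10 (adjusted p = 0.16). NF-kB target genes fell in 15 and 14 of 19 cases (17 and 16 adjusted over the list alone; median −0.83 and −0.79, adjusted p = 2.45e-36 and 1.41e-31). Secretory genes fell in 10 and 10 of 31 with 1 rising (median −0.22 and −0.27), and interferon response genes in 4 and 2 of 29 (median −0.18 and −0.23, adjusted p = 0.00103 and 0.000374). The antigen presentation list was lower with AZD1152 (median −0.15, adjusted p = 0.0128), a call not kept (adjusted p = 0.0502 with an estimated correlation).

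At 18 h, most DNA replication genes had fallen, while few mitotic genes were called. Of the 46 replication genes, 35 fell with AZD1152 and 34 with SNS-314 (35 each adjusted over the list alone), with medians of −0.65 and −0.69 (adjusted p = 1.84e-28 and 5.78e-42), −0.61 and −0.67 with the slide as a block. MCM10, which encodes a replication initiation factor, fell by 1.35 ± 0.14 and by 1.23 ± 0.14, and E2F2 fell by 1.32 ± 0.13 and by 1.39 ± 0.13. Among 47 mitotic genes 2 rose and 4 fell with AZD1152 and 2 rose and 2 fell with SNS-314 (2 up and 5 down, and 2 up and 3 down, adjusted over the list alone), and the list did not pass (median −0.05 and −0.01, adjusted p = 0.566 and 0.873). KIF20A rose by 0.69 ± 0.12 and 0.48 ± 0.12, and PTTG1, the securin gene, by 0.64 ± 0.10 and 0.41 ± 0.10. The SNS-314 calls ended without replicate 1 for KIF20A (0.40) and replicate 3 for PTTG1 (0.34). CDKN1A rose by 0.59 ± 0.10 and 0.45 ± 0.10. With median centring the SNS-314 calls of KIF20A, PTTG1 and CDKN1A ended, although the rises were larger (0.74, 0.65 and 0.65; adjusted p = 0.0588, 0.0895 and 0.073). The largest rises were in NPPC (1.47 ± 0.19 and 1.30 ± 0.19), TMEFF2 (1.40 ± 0.18 and 1.42 ± 0.18), TRIM9 with AZD1152 (1.42 ± 0.10) and LYPD1 with SNS-314 (1.30 ± 0.21).

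Of the p53 target genes, 14 rose and 1 fell with AZD1152 at 18 h and 8 rose with SNS-314 (15 up and 1 down, and 17 up, adjusted over the list alone). Their medians were 0.51 and 0.41 (adjusted p = 2.51e-07 and 4.14e-09), 0.35 and 0.36 with the slide as a block. CXCL1 fell by 3.23 ± 0.44 with AZD1152 and by 2.40 ± 0.44 with SNS-314, CCL2 by 2.75 ± 0.17 and by 2.05 ± 0.17. CXCL8 fell by 2.64 ± 0.18 and by 1.32 ± 0.18, IL6 by 2.60 ± 0.14 and by 1.78 ± 0.14, and ZC3H12A with SNS-314 by 1.82 ± 0.19. NF-kB target genes fell in 15 and 12 cases (15 and 15 adjusted over the list alone; median −0.80 and −0.65, adjusted p = 8.48e-19 and 2.44e-17). Secretory genes fell in 10 and 9 with 2 and 1 rising. Interferon response genes had medians of −0.27 and −0.25 (adjusted p = 0.00287 and 4.05e-06; 0.0775 as the adjusted p with an estimated correlation for AZD1152). ER stress and integrated stress response genes rose in 6 and 7 of 22 cases (8 and 11 adjusted over the list alone; median 0.27 and 0.30, adjusted p = 0.00287 and 6.75e-08). The AZD1152 call was lost (adjusted p = 0.173 with an estimated correlation). Also lost were the hypoxia list with AZD1152 (adjusted p = 0.037, against 0.0869 with an estimated correlation) and the immediate-early list with SNS-314 (adjusted p = 0.0091, against 0.0544 with an estimated correlation). Without AZD1152 replicate 1, AZD1152 called 1095 probes at 18 h in place of 2049.

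At 24 h, mitotic genes and genes of the chromosomal passenger complex had fallen along with the replication genes. AURKB, which encodes Aurora kinase B, fell by 1.03 ± 0.16 with AZD1152 and by 1.05 ± 0.16 with SNS-314 (adjusted p = 1.2e-05 and 7.8e-06). The proliferation marker gene MKI67 fell by 0.80 ± 0.18 and by 0.87 ± 0.18, TOP2A, a topoisomerase gene of dividing cells, by 0.80 ± 0.16 and by 0.83 ± 0.16, and CDK1, the gene for the main mitotic kinase, by 1.15 ± 0.16 and by 0.98 ± 0.16. AURKA fell by 0.35 ± 0.11 and by 0.38 ± 0.11 (adjusted p = 0.042 and 0.023) and BIRC5, the survivin gene, by 0.33 ± 0.11 with AZD1152 (adjusted p = 0.049). The AURKA calls ended without AZD1152 replicate 3 or 4 (−0.29 and −0.32) or control replicate 2, 3 or 4 (−0.35, −0.34 and −0.31), and without SNS-314 replicate 3 or 4 (−0.32 and −0.35) or control replicate 3 or 4 (−0.36 and −0.34). The BIRC5 call ended without AZD1152 replicate 1, 2 or 3 (−0.33, −0.29 and −0.32) or any control replicate (−0.31, −0.35, −0.31 and −0.36). The AURKA call of AZD1152 also ended with the slide as a block. With median centring every call named in this paragraph so far ended, while the lists that follow passed. AURKB was then at −0.70 and −0.82 (adjusted p = 0.0744 and 0.051), MKI67 at −0.42 and −0.58, TOP2A at −0.52 and −0.63, CDK1 at −0.84 and −0.76, AURKA at −0.07 and −0.17 and BIRC5 at −0.03. Of the 47 mitotic genes, 22 fell and 1 rose with AZD1152 and 25 fell with SNS-314 (33 down and 1 up, and 31 down and 1 up, adjusted over the list alone; median −0.46 and −0.47, adjusted p = 1.45e-15 and 3.15e-15). Of the 9 passenger complex genes, 7 and 6 fell (8 and 7 adjusted over the list alone; median −0.45 and −0.40, adjusted p = 9.67e-06 and 2.8e-05). Also, 39 of the 46 replication genes fell with each drug (42 and 40 adjusted over the list alone; median −0.77 and −0.73, adjusted p = 1.46e-41 and 3.4e-37). With the slide as a block these medians were −0.45 and −0.44, −0.38 and −0.41, and −0.75 and −0.77, and within slides 1 and 2 the mitotic medians were −0.48 and −0.31 for AZD1152 and −0.52 and −0.28 for SNS-314.

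The largest rises at 24 h were in FABP7, a fatty acid binding protein gene (at least 2.04-fold and at least 1.88-fold), the methyltransferase gene INMT (at least 1.77-fold and at least 2.28-fold) and the carboxypeptidase gene CPVL (1.57 ± 0.13 and 1.64 ± 0.13). Of the p53 target genes 15 and 14 rose (18 and 17 adjusted over the list alone; median 0.49 with each drug, adjusted p = 4.24e-12 and 8.23e-12), and CDKN1A rose by 0.64 ± 0.10 and 0.63 ± 0.10. CXCL1 fell by 3.44 ± 0.44 and by 3.21 ± 0.44, CXCL8 by 2.83 ± 0.18 and by 2.56 ± 0.18, IL6 by 2.59 ± 0.14 and by 2.33 ± 0.14, and CCL2 by 2.50 ± 0.17 and by 2.67 ± 0.17. Of the NF-kB target genes 14 and 15 fell (16 each adjusted over the list alone; median −0.68 and −0.87, adjusted p = 7.26e-17 and 1.34e-18). ER stress genes rose in 6 and 8 cases (8 and 9 adjusted over the list alone; median 0.29 and 0.27, adjusted p = 8.66e-05 and 6.62e-06). Cholesterol biosynthesis genes rose in 4 and 7 of 19 cases (4 and 13 adjusted over the list alone; median 0.19 and 0.45, adjusted p = 0.00725 and 3.65e-06), the AZD1152 call lost (adjusted p = 0.0733 with an estimated correlation). Nuclear lamina and chromatin genes fell in 5 of 16 cases with each drug (median −0.30 and −0.21, adjusted p = 0.000417 and 0.000769). Markers of endothelial cells and fibroblasts were higher (median 0.35 and 0.26, adjusted p = 0.00587 and 0.0434; 0.063 as the adjusted p with an estimated correlation for SNS-314). Interferon response genes were lower (median −0.18 and −0.14, adjusted p = 0.0237 and 0.0281), a call lost under both drugs (adjusted p = 0.138 and 0.14 with an estimated correlation). So was the antigen presentation list with SNS-314 (adjusted p = 0.0268, against 0.0684 with an estimated correlation). MITF, the master regulator gene of melanocytes, was detected on 3 of 4 SNS-314 arrays and on 0 of 4 control arrays (adjusted p = 0.011), and with median centring the call ended (adjusted p = 0.101).

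At 48 h, genes of DNA replication and mitosis had fallen nearly throughout their lists. Of the 46 replication genes, 44 fell with AZD1152 and 43 with SNS-314 (44 each adjusted over the list alone), with medians of −1.39 and −1.36 (adjusted p = 3.4e-42 and 2.54e-41). All 47 mitotic genes and all 9 genes of the passenger complex and Aurora kinases fell with each drug, over all probes and adjusted over the list alone. Their medians were −1.02 and −1.02 (adjusted p = 3.99e-30 and 5.82e-28) and −1.17 and −1.20 (adjusted p = 2.98e-10 and 1.11e-09). With the slide as a block the 3 lists' medians were −1.35 and −1.36, −1.04 and −1.02, and −1.17 and −1.21, and within slides 1 and 2 the replication medians were −1.27 and −1.37 for AZD1152 and −1.41 and −1.44 for SNS-314. The lists' directions held with median centring.

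The deepest fall at 48 h was in ID1, which encodes an inhibitor of differentiation factors, from 10.36 ± 0.21 (SD, n = 4) to 7.40 ± 0.11 with AZD1152 (−2.96 ± 0.15, adjusted p = 6e-18) and with SNS-314 by 2.86 ± 0.15 (adjusted p = 1.9e-17). Its relative ID3 fell by 1.94 ± 0.16 and by 2.13 ± 0.16. Replication genes made up much of the rest. With AZD1152 the ribonucleotide reductase gene RRM2 fell by 2.26 ± 0.24, the helicase gene MCM5 by 2.02 ± 0.16, E2F2 by 2.01 ± 0.13, GINS3 by 1.97 ± 0.15 and GINS2 by 1.95 ± 0.12. TEDC2, a centriole gene, fell by 1.99 ± 0.15, CHAF1A was at least 2.80-fold lower and HYI at least 3.10-fold lower. With SNS-314 CHAF1B fell by 2.27 ± 0.18, E2F2 by 2.19 ± 0.13, GINS2 by 2.16 ± 0.12, and the licensing factor gene CDT1 by 2.15 ± 0.15. The exonuclease gene EXO1 fell by 2.12 ± 0.14, MCM10 by 2.08 ± 0.14 and MCM2 by 2.06 ± 0.14, and CHAF1A was at least 2.75-fold lower. AURKB fell from 11.43 ± 0.11 to 9.75 ± 0.16 with AZD1152 (−1.68 ± 0.16, adjusted p = 6.9e-11; within slides 1 and 2, −1.50 and −1.79) and by 1.67 ± 0.16 with SNS-314. AURKA fell by 1.08 ± 0.11 and by 0.95 ± 0.11, and BIRC5 by 1.17 ± 0.11 and by 1.24 ± 0.11. TOP2A fell by 1.07 ± 0.16 and by 1.15 ± 0.16, and the cyclin B1 gene CCNB1 by 0.81 ± 0.14 and by 0.76 ± 0.14. MKI67 was at least 2.80-fold and at least 2.76-fold lower. INCENP, the scaffold gene of the passenger complex, fell by 0.68 ± 0.23 and by 0.78 ± 0.23 (adjusted p = 0.022 and 0.0085). The AZD1152 call ended without AZD1152 replicate 2 or 4 (−0.62 and −0.66) or control replicate 1, 2 or 4 (−0.50, −0.54 and −0.57), and the SNS-314 call without control replicate 1 (−0.59). The INCENP calls (−0.51 and −0.60) and CCNB1 calls (−0.56 and −0.52) ended with median centring. Without control replicate 3, far below the other controls, INCENP stood at −1.13 and −1.22.

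**Figure D2:**
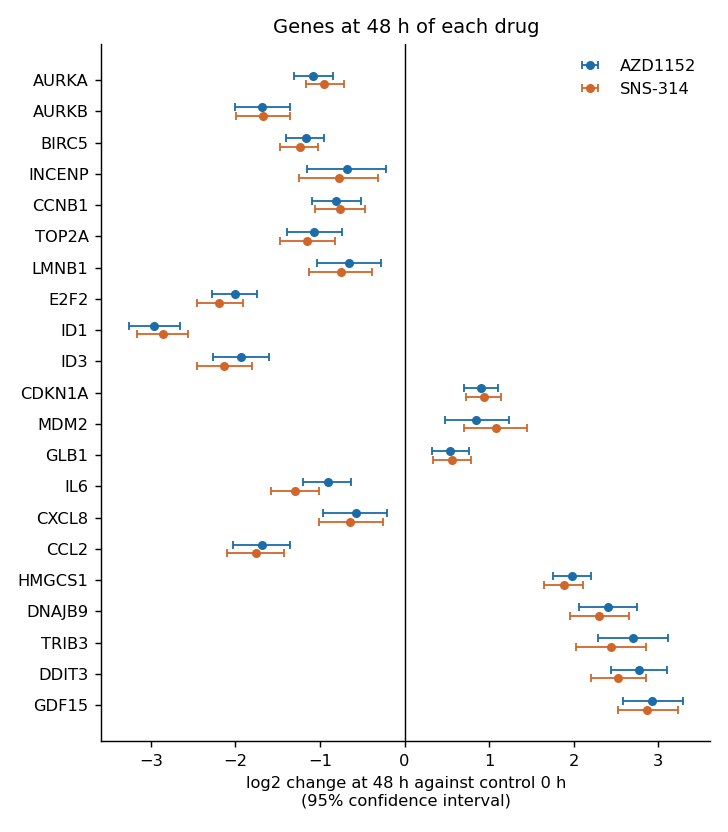
Log2 change at 48 h against the control for 21 genes, with 95% confidence intervals, for AZD1152 and SNS-314. AURKB lies at −1.68 and −1.67, CDKN1A at 0.90 and 0.94 and GDF15 at 2.93 and 2.87.

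Growth arrest and senescence genes moved as follows at 48 h. CDKN1A rose by 0.90 ± 0.10 with AZD1152 and 0.94 ± 0.10 with SNS-314 (adjusted p = 4.4e-09 and 1.6e-09), and MDM2, a p53 target that encodes its ubiquitin ligase, rose by 0.85 ± 0.18 and 1.08 ± 0.18. Of the p53 target genes 17 and 20 rose (18 and 20 adjusted over the list alone), with medians of 0.58 and 0.75 (adjusted p = 6.63e-08 and 1.17e-09), 0.54 and 0.78 with the slide as a block. SPATA18, a mitochondrial quality control gene, rose by 1.48 and 1.79. Of 8 CDK inhibitor and Rb family genes, 1 and 2 rose and 2 fell (2 up and 3 down with each drug adjusted over the list alone; median −0.15 and −0.15, adjusted p = 0.476 and 0.479). CDKN2D was at −0.95 under both drugs and RBL1 at least 2.74-fold and at least 2.70-fold lower. LMNB1, whose loss is a common mark of senescence, fell by 0.66 ± 0.19 and by 0.75 ± 0.19 (adjusted p = 0.0063 and 0.0016), calls that ended with median centring (−0.39 and −0.48, adjusted p = 0.354 and 0.233). Nuclear lamina and chromatin genes fell in 8 and 10 of 16 cases (8 and 10 adjusted over the list alone; median −0.43 and −0.42, adjusted p = 5.02e-06 and 4.45e-06; −0.46 and −0.48 with the slide as a block). The lamina gene TMPO was at −1.45 and the histone methyltransferase genes SUV39H1 at −1.42 and EZH2 at −1.39 with AZD1152. GLB1, which encodes the enzyme behind senescence-associated beta-galactosidase staining, rose by 0.54 ± 0.11 and 0.56 ± 0.11 (adjusted p = 0.00015 and 9.6e-05). Lysosome and autophagy genes rose in 13 and 16 of 25 cases, with 1 falling (15 and 18 up and 1 down adjusted over the list alone; median 0.34 and 0.48, adjusted p = 6.29e-05 and 9.34e-06; 0.42 and 0.45 with the slide as a block). The autophagy gene WIPI1 was at 1.46 and 1.54. Histone genes went both ways, with 2 up and 3 or 4 down of 12 (median −0.30 and −0.28, adjusted p = 0.107 and 0.0726), and passed as a list with the slide as a block (adjusted p = 0.0327 and 0.0202).

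Stress response genes were among the largest rises at 48 h. GDF15 rose from 9.70 ± 0.09 to 12.63 ± 0.23 with AZD1152 (SD, n = 4; 2.93 ± 0.17, adjusted p = 6.3e-16) and by 2.87 ± 0.17 with SNS-314. DDIT3, which encodes the stress transcription factor CHOP, rose by 2.77 ± 0.16 and 2.53 ± 0.16, TRIB3, a pseudokinase gene induced by it, by 2.70 ± 0.20 and 2.44 ± 0.20, and DNAJB9, an ER chaperone gene, by 2.41 ± 0.17 and 2.30 ± 0.17. In all, 21 of 22 ER stress and integrated stress response genes rose with each drug, over all probes and adjusted over the list alone (median 1.24 and 1.21, adjusted p = 2.01e-21 and 1.44e-19). The medians were 1.31 and 1.22 with the slide as a block, and within slides 1 and 2 they were 1.30 and 1.18 for AZD1152 and 1.18 and 1.21 for SNS-314. Of 19 cholesterol biosynthesis genes, 15 rose with each drug (16 adjusted over the list alone; median 0.90 and 1.01, adjusted p = 1.86e-11 and 1.85e-11; 0.85 and 0.94 with the slide as a block). HMGCS1, the HMG-CoA synthase gene, was at 1.98 ± 0.11 and 1.88. Further large rises were in FABP7 (at least 3.76-fold and 3.84-fold), CPVL (2.21 ± 0.13 and 2.29 ± 0.13), MCF2L, a guanine exchange factor gene (2.03 ± 0.20 and 2.20 ± 0.20), and CTH, a cysteine synthesis gene (at least 2.39-fold and 2.27-fold). The neuropeptide gene TAC1 rose with AZD1152 (2.01 ± 0.19), and INMT (at least 2.37-fold) and the collagen gene COL15A1 (at least 2.13-fold) rose with SNS-314. Heat shock genes fell instead, in 8 and 11 of 14 cases (11 and 12 adjusted over the list alone; median −0.44 and −0.45, adjusted p = 0.00124 and 0.00298; −0.43 and −0.40 with the slide as a block). Cytoskeleton genes fell in 6 and 8 of 22 with 1 rising (8 and 9 down adjusted over the list alone; median −0.24 and −0.25, adjusted p = 0.00619 and 0.0195). The SNS-314 call was lost (adjusted p = 0.0836 with an estimated correlation). The microtubule regulator gene STMN1 was at −1.31 with AZD1152.

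The inflammatory genes stood nearer to the control at 48 h than at earlier times. CCL2 fell by 1.69 ± 0.17 and by 1.76 ± 0.17, and IL6 fell by 0.91 ± 0.14 and by 1.30 ± 0.14. CXCL8 fell by 0.58 ± 0.18 and by 0.64 ± 0.18 (adjusted p = 0.015 and 0.0069), the CXCL8 calls ending with median centring (−0.38 and −0.45). NF-kB target genes fell in 5 and 7 of 19 cases, with 1 rising under SNS-314, and the list did not pass (median −0.22 and −0.23, adjusted p = 0.136 and 0.12). Senescence-associated secretory genes went both ways, with 7 up and 5 down for AZD1152 and 9 up and 6 down for SNS-314 (8 and 6, and 11 and 6, adjusted over the list alone; median 0.15 and 0.14, adjusted p = 0.45 and 0.455). Interferon response genes rose in 12 and 8 of 29 cases with 3 falling (14 and 8 up and 3 down adjusted over the list alone; median 0.30 and 0.22, adjusted p = 0.0188 and 0.0923). The AZD1152 call was lost (adjusted p = 0.116 with an estimated correlation). TRIM22 rose by 1.03 and 1.22 and IFIT1 by 0.96 and 0.88, both genes of antiviral defence, while USP18, an inhibitor of interferon signalling, was at −0.86 and −0.75. Among 16 antigen presentation genes 1 rose with each drug, HLA-DMA (0.94 and 0.81; list median −0.04 and 0.00, adjusted p = 0.799 and 0.773). Of 8 melanocyte lineage genes 2 fell (median −0.07 and −0.02, adjusted p = 0.374 and 0.588), including the melanocortin receptor gene MC1R at −0.56 and −0.53. The USP18 calls (−0.53 and −0.39) and MC1R calls (−0.33 and −0.32) ended with median centring. MITF was detected on 1 and 2 of 4 treated arrays and on 0 of 4 control arrays, and was not called (adjusted p = 0.96 and 0.17). Neural crest and invasive melanoma genes went both ways, with 1 up and 5 down and 4 up and 4 down of 15 (median 0.21 and 0.18, adjusted p = 0.907 and 0.998), with the N-cadherin gene CDH2 at −0.91 and −1.07. Ribosomal protein genes served as a steady class, with 2 of 33 falling under each drug (median 0.03 and −0.01, adjusted p = 0.916 and 0.861). Markers of endothelial cells and fibroblasts, a check for other cells, had 3 and 4 of 4 genes higher (4 each adjusted over the list alone; median 0.36 and 0.45, adjusted p = 0.0634 and 0.0325; 0.40 and 0.47 with the slide as a block). The SNS-314 call ended with median centring (adjusted p = 0.0614).

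**Figure D3:**
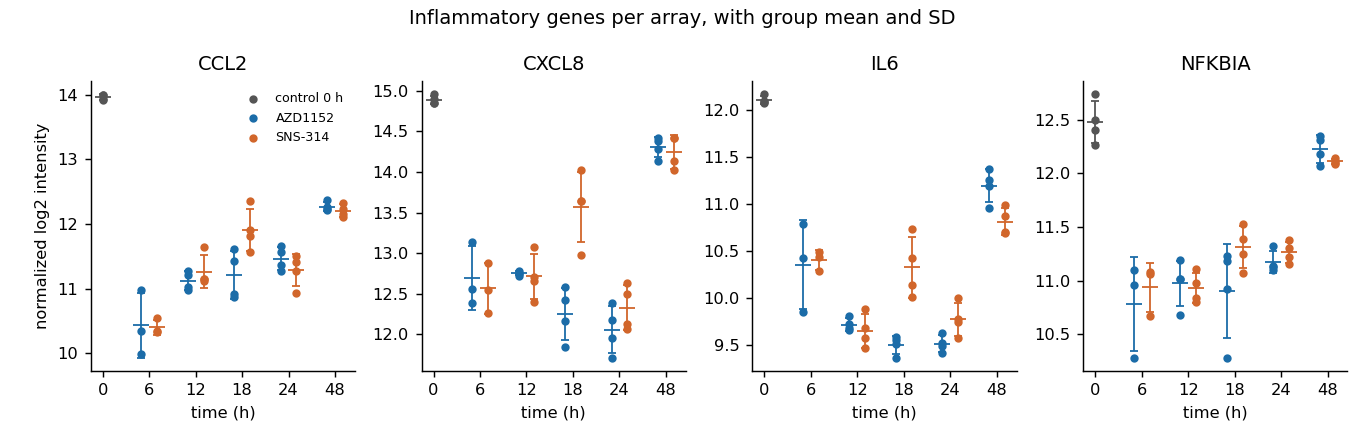
Normalized log2 level of CCL2, CXCL8, IL6 and NFKBIA on each array by time in h, with the group mean and SD, for AZD1152, SNS-314 and the control at 0 h. CCL2 fell from a control mean of 13.96 to 10.44 with AZD1152 at 6 h and stood at 12.27 at 48 h.

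**Figure D4:**
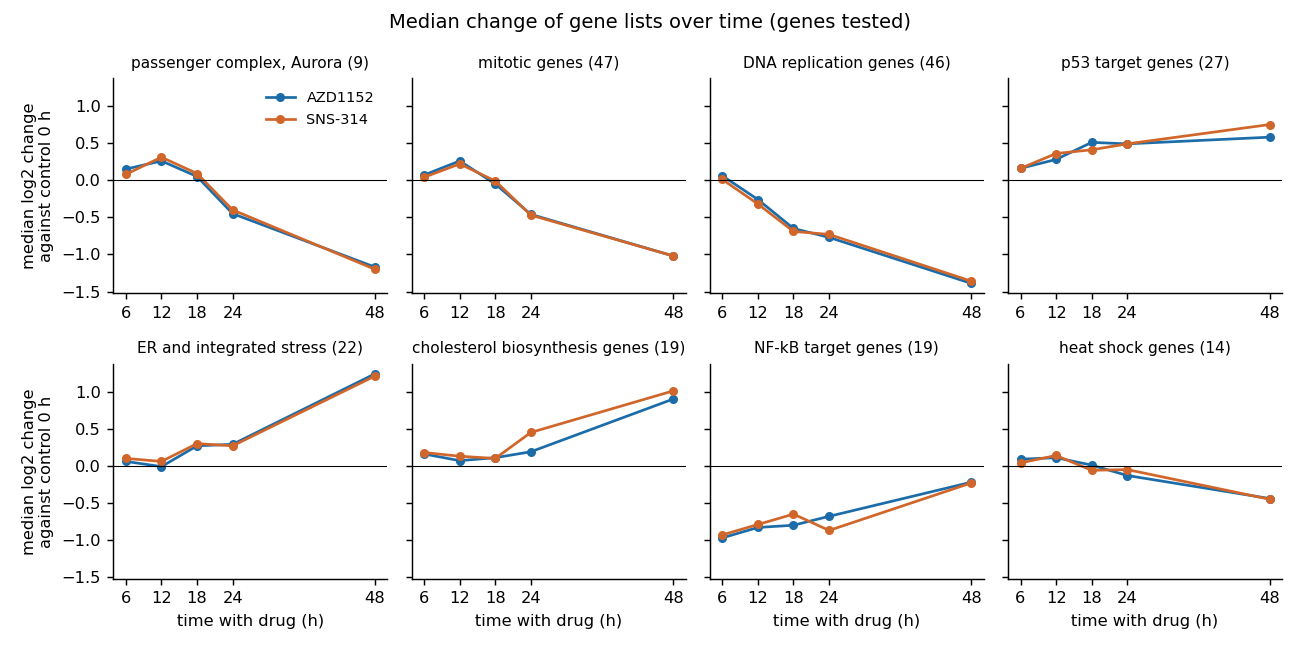
Median log2 change of selected gene lists against the control at 6, 12, 18, 24 and 48 h, for AZD1152 and SNS-314. Shown are the passenger complex and Aurora kinase, mitotic, DNA replication, p53 target, ER stress, cholesterol biosynthesis, NF-kB target and heat shock lists. The other lists are not shown. NF-kB target genes were lowest at 6 h (−0.97 and −0.93), and DNA replication genes at 48 h (−1.39 and −1.36).

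At 48 h the slide block kept 107 of 108 calls of named genes for AZD1152, losing RPS16, and 107 of 109 for SNS-314, losing IRF1 and CRIM1, and moved log2 changes by at most 0.46 and 0.45. At 24 h it kept 68 of 75 calls for AZD1152, losing CDCA2, H2BC21, TAP2, MSMO1, SQLE, SLC2A1 and AURKA, and 78 of 82 for SNS-314, losing GLA, THBS1, CCN1 and BID. At 18 h it kept 61 of 62, losing ATP6V1H, and 49 of 49, at 12 h 35 of 37, losing SLC2A1 and EGR3, and 37 of 39, losing TPX2 and CEBPB, and at 6 h all 26 and all 35. Median centring in place of quantile normalization moved the median log2 change of all tested probes to between 0.14 and 0.28 for AZD1152 at all times and for SNS-314 from 12 h. The changes given here are relative to quantile-normalized arrays. At 6, 12, 18, 24 and 48 h median centring kept 13 of 26, 11 of 37, 39 of 62, 36 of 75 and 81 of 108 calls of named genes for AZD1152 and 14 of 35, 12 of 39, 26 of 49, 32 of 82 and 84 of 109 for SNS-314. Under median centring AZD1152 called 2957 probes at 48 h (82.5% of them higher, against 50.7%) and SNS-314 called 3245 (82.1% higher, against 51.9%). Centring over detected probes, an alternative added later, moved the shares the other way. It called 5010 probes for AZD1152 (38.2% higher) and 5513 for SNS-314 (37.7% higher).

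The changes under the drugs were compared across all tested probes, which share their control arrays. The correlation between the log2 changes was 0.71 at 6 h, 0.73 at 12 h, 0.80 at 18 h, 0.88 at 24 h and 0.95 at 48 h, across probes, which are not independent replicates. Unchanged groups simulated against the same controls gave 0.43 at 6 h and 0.50 at the later times. The covariances were 0.0399, 0.0425, 0.0634, 0.0830 and 0.192, which exceed the simulated covariance by 0.0258, 0.0284, 0.0493, 0.0691 and 0.178. With the controls split 2 and 2 between the drugs, the correlation was 0.27 to 0.47, 0.28 to 0.46, 0.45 to 0.60, 0.60 to 0.69 and 0.79 to 0.85. Neither the simulation nor these splits cover the slides that the drugs share, where deviations from the group means correlated with a median of 0.18. The part of each correlation that comes from the slides was not estimated. At 48 h, 2319 probes were called higher under both drugs and 2271 lower under both, and 0 were called in opposite directions. Independent lists would share 452.1 and 407.4, but these lists share their controls; with the controls split, 1341 to 1446 were higher and 1461 to 1514 lower under both. At 6 h the shared calls were 112 higher and 115 lower, and 40 to 47 and 68 to 72 with the controls split. Lower under both drugs were CCL2, CXCL1, CXCL8, IL6 and ICAM1.

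The drugs were then set against each other at each time, AZD1152 minus SNS-314. At 18 h limma called 5 probes, all lower with AZD1152. A CXCL8 probe differed by −1.32 ± 0.18 (12.25 ± 0.32 against 13.57 ± 0.44, SD, n = 4 each; adjusted p = 0.000144). A further CXCL8 probe differed by −1.05 (adjusted p = 0.0092) and IL6 by −0.82 ± 0.14 (9.51 ± 0.10 against 10.33 ± 0.33; adjusted p = 0.00558), the IL6 call ending without SNS-314 replicate 3 (−0.68). The other 2 probes have no listed gene and differed by −1.48 and −0.93 (adjusted p = 0.0092 and 0.000144). CCL2 was at −0.70 ± 0.17 (adjusted p = 0.18). With the slide as a block 15 probes were called, and 0 without 3 arrays picked by eye or with only the arrays compared. Leaving out 1 array gave 3, 13, 76 and 3 probes without AZD1152 replicates 1 to 4 and 8, 3 and 9 without SNS-314 replicates 1, 3 and 4. With median centring the CXCL8 and IL6 calls ended (adjusted p = 0.0842 and 1) at differences that hardly moved (−1.28 and −0.78). Limma called 0 probes at 6, 12, 24 and 48 h, with 680, 1135, 635 and 574 at an unadjusted p under 0.05, and 0 with the slide as a block. At 48 h the differences of the Aurora kinase genes were −0.13 for AURKA (95% interval −0.36 to 0.09) and −0.02 for AURKB (−0.33 to 0.30). The 95% interval of the difference lay within 2-fold for 98.6%, 99.4%, 99.4%, 99.7% and 99.8% of probes at 6, 12, 18, 24 and 48 h, and within 1.5-fold for 73.3%, 81.3%, 80.8%, 86.5% and 86.9%.

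Some gene lists differed slightly between the drugs. Cholesterol biosynthesis genes were lower with AZD1152 than with SNS-314 at 24 h (median −0.12, adjusted p = 5.22e-05; −0.21, −0.24, −0.09 and −0.12 within slides 1 to 4). So were p53 target genes at 48 h (median −0.05, adjusted p = 0.00727; 0.00, −0.16 and −0.08 within slides 1, 2 and 3), a call that ended with median centring (adjusted p = 0.0565). NF-kB target genes were lower with AZD1152 at 18 h (median −0.19, adjusted p = 0.000762; −0.03, −0.15, −0.25 and −0.04 within slides 1 to 4), but the call was lost (adjusted p = 0.551 with an estimated correlation). DNA replication genes were higher with AZD1152 at 48 h (median 0.06, adjusted p = 0.00727; 0.12, 0.08 and 0.06 within slides 1, 2 and 3), a call also lost (adjusted p = 0.099 with an estimated correlation).

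Comparing 48 h with 6 h within each drug sets treated cells against treated cells. No untreated cells were measured at these times, so these differences too include whatever the time in culture did. At 48 h 5307 probes differed from 6 h with AZD1152 (2678 higher, 2629 lower) and 6029 with SNS-314 (3082 and 2947). Of these, 975 and 1105 moved at least 2-fold, and the slide block gave 6098 and 6904. The largest rises were in C11orf96 (3.04 ± 0.16 and 2.92 ± 0.16), TRIB3 (2.81 and 2.52), GDF15 (2.72 and 2.43), TCIM (at least 3.24-fold and 3.30-fold), DDIT3 with AZD1152 (2.57) and FABP7 with SNS-314 (at least 4.30-fold). The deepest falls were in ID1 (−2.98 and −3.07), ID3 (−2.30 and −2.61) and the ubiquitin ligase gene MARCHF4 (−2.46 and −2.81), followed by RRM2 (−2.65) and the thioredoxin inhibitor gene TXNIP (−2.36) with AZD1152, and in DDAH1 and the potassium channel gene KCNH1 (−2.52 each) with SNS-314. CCL2 rose by 1.83 ± 0.18 and 1.80 ± 0.18 and CXCL8 by 1.61 ± 0.20 and 1.69 ± 0.20. IL6 rose by 0.84 ± 0.15 with AZD1152 and by 0.41 ± 0.15 with SNS-314 (adjusted p = 0.035), where the call ended without SNS-314 6 h replicate 2 or 3 (0.35 and 0.43) or SNS-314 48 h replicate 1 or 2 (0.35 and 0.39). Of 19 NF-kB target genes 14 and 15 rose, over all probes and adjusted over the list alone (median 0.88 and 0.79, adjusted p = 1.83e-08 and 3.81e-07; 0.89 and 0.79 with the slide as a block; 0.74, 0.96 and 1.09 within slides 1, 2 and 3 for AZD1152 and 0.94, 0.58 and 0.76 for SNS-314). Of 31 secretory genes 17 and 19 rose and 1 and 2 fell (median 0.44 and 0.50, adjusted p = 5.45e-07 and 1.03e-07). Interferon response genes rose in 18 and 15 of 29 cases with 1 falling (median 0.44 and 0.55, adjusted p = 8.24e-06 and 4.18e-06). AURKB fell by 1.75 and by 1.78, AURKA by 1.23 and by 1.07 and LMNB1 by 1.04 and by 0.98, while CDKN1A rose by 0.70 and 0.74, MDM2 by 1.02 and 1.37 and GLB1 by 0.41 and 0.45, its AZD1152 call ending without AZD1152 6 h replicate 1 (0.35). With median centring the calls of GLB1 ended under both drugs, although the rises were larger (0.49 and 0.54), and so did those of IL6 (0.54) and LMNB1 (−0.81) under SNS-314. Passenger complex, mitotic and replication genes fell as lists (medians −1.27 and −1.28, −1.05 and −0.98, and −1.50 and −1.46), as did heat shock genes (−0.53 and −0.44), lamina and chromatin genes (−0.52 and −0.45) and cytoskeleton genes (−0.36 and −0.30). Rising as lists were p53 target genes (0.43 and 0.61), ER stress genes (1.05 and 1.00), cholesterol genes (0.81 and 0.66) and lysosome genes (0.38 and 0.45). The histone list was lower with each drug (adjusted p = 0.0363 and 0.0468), a call lost under both (adjusted p = 0.129 and 0.155 with an estimated correlation). For the change from 6 to 48 h between the drugs, limma called 0 probes, with 809 at an unadjusted p under 0.05, and no list passed.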

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

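The tests of explanations and the splits of arrays in this part were chosen after the results were seen.

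NF-kB target genes, which respond to inflammatory signals, were lower than in the control at 6 h with both drugs, with a median change of −0.97 for AZD1152 and −0.93 for SNS-314. A difference between slides is argued against, since the weakest median within slide 1 or 2 under either drug was −0.83. Normalization between arrays is argued against too: the medians were −0.74 and −0.76 with median centring and −0.95 and −0.85 with centring over detected probes. The weakest under any other processing was −0.57, with no background correction or with the authors' values. Time in culture or handling shared by every treated array cannot be told apart from the drugs, because there were 0 untreated arrays at 6 h. From 6 to 48 h the members rose by a median of 0.88 and 0.79, so a transient effect of either the drugs or the handling stays open.

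CXCL8 and IL6, which encode inflammatory cytokines, were lower with AZD1152 than with SNS-314 at 18 h (−1.32 and −0.82), and 5 probes differed in a direct test between the drugs. The weakest median difference of these probes within 1 slide was −0.78, which decides nothing about slides, since the probes were chosen for this difference. Each of slides 1 to 4 holds 1 array of each drug at 18 h, so a shift of a whole slide falls on both drugs alike. Without 3 arrays picked by eye from the principal components, with no fixed rule (AZD1152 18 h replicates 1 and 4 and SNS-314 12 h replicate 4), the median difference was −0.87, against −1.05 with them. SNS-314 12 h replicate 2, which was kept, lay further from its group mean than SNS-314 12 h replicate 4 (0.268 against 0.261). The CXCL8 call ended at −1.07 ± 0.21, against −1.32 ± 0.18, and the IL6 call at −0.87 ± 0.18, against −0.82 ± 0.14 (adjusted p = 0.0998 each). The other 3 calls ended too. A further CXCL8 probe hardly moved from −1.05 (adjusted p = 0.428), and 1 probe without a listed gene went from −1.48 to −0.85. The probes were chosen for this difference, partly on arrays that were kept. The remaining differences therefore do not decide how much these arrays contributed. IL6 also lost its call without SNS-314 18 h replicate 3 (−0.68), and CXCL8 and IL6 lost theirs with median centring (−1.28 and −0.78). A difference between the drugs or their doses stays open as a hypothesis.

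Markers of endothelial cells and fibroblasts were higher at 48 h, with a median change of 0.45 for SNS-314 (adjusted p = 0.0325, and 0.0614 with median centring) and of 0.36 for AZD1152, where the list did not pass (adjusted p = 0.0634). Of 9 other listed genes, abundant collagen genes among them, 0 were detected on at least 4 of the 8 arrays at 48 h. COL1A1, DCN, LUM, THY1, PECAM1, CDH5 and KDR were detected on 0 and COL3A1 and TEK on 1. These 9 are the listed genes without a tested probe, and every probe detected on at least 3 arrays was tested. The count of 0 was therefore fixed in advance. It does not decide whether RNA from fibroblasts or endothelial cells was present. The 4 listed genes that were tested are those behind the higher medians. A difference between slides is argued against by a lowest median of 0.35 within slide 1 or 2. RNA from other cells and a change in the melanoma cells themselves both stay open as hypotheses.

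Further results differed between the drugs or times in a direct test. Cholesterol biosynthesis genes at 24 h (median difference AZD1152 minus SNS-314 −0.12) and p53 target genes at 48 h (−0.05) differed as lists, and kept the call with an estimated correlation (adjusted p = 0.0286 and 0.0136); the p53 call ended with median centring (adjusted p = 0.0565). NF-kB target genes at 18 h (−0.19) and DNA replication genes at 48 h (0.06) lost it (adjusted p = 0.551 and 0.099). Between 48 h and 6 h 5307 probes differed with AZD1152 and 6029 with SNS-314.

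Single arrays lay far from the others of their group in 19 of 510 groups of 4 values, where chance gives about 1 in 20. For gene levels in the control these were INCENP (6.79 in replicate 3, against 8.46 to 8.67), CHAF1A (8.73 in replicate 1, against 8.48 to 8.52), NNMT (8.97 in replicate 1, against 8.54 to 8.60), LYPD1 (7.89 in replicate 2, against 7.60 to 7.64) and CCNB1 (10.85 in replicate 2, against 10.89 to 10.90). With AZD1152 they were AURKB at 18 h (11.96 in replicate 1, against 11.11 to 11.21) and, at 48 h, ID1 (7.57 in replicate 2, against 7.33 to 7.36) and MCM5 (8.79 in replicate 1, against 8.58 to 8.62). With SNS-314 they were CCL2 at 12 h (11.64 in replicate 4, against 11.12 to 11.15), AURKA at 18 h (12.34 in replicate 4, against 12.90 to 12.93) and, at 48 h, MCM2 (8.15 in replicate 1, against 7.98 to 8.01) and MDM2 (9.82 in replicate 2, against 9.34 to 9.36). For means of lists they were YAP target genes with AZD1152 at 12 h (9.62 in replicate 3, against 9.50 to 9.51), immune cell markers with AZD1152 at 48 h (7.87 in replicate 1, against 7.80 to 7.81), extracellular matrix genes with SNS-314 at 12 h (11.21 in replicate 1, against 11.34 to 11.36) and 48 h (11.25 in replicate 3, against 11.40 to 11.43), ribosomal protein genes with SNS-314 at 12 h (13.70 in replicate 2, against 13.73), antigen presentation genes with SNS-314 at 24 h (10.45 in replicate 1, against 10.27 to 10.30), and endothelial and fibroblast markers in the control (9.59 in replicate 2, against 9.52 to 9.53).

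Other splits of the same arrays were counted for each number of changed probes. For every drug and time against the control, 1 of 35 splits, the real one, called as many probes. This is the lowest share that 35 splits can reach. These comparisons share the 4 control arrays, and no allowance was made for their number. The controls lie only on slides 1 and 2 and the splits do not keep to the slides, so neither chance nor the slides are excluded. The highest of the other splits was 91, 1, 59, 3 and 74 for AZD1152 at 6, 12, 18, 24 and 48 h, against 288, 421, 2049, 1972 and 5407, and 116, 181, 3, 12 and 37 for SNS-314, against 415, 549, 1042, 2279 and 5981. The same held for 48 h against 6 h, with 2892 as the highest other against 5307 for AZD1152 and 3471 against 6029 for SNS-314, in splits that keep all but 1 array of a time together. Between the drugs at 18 h the real split gave 5 probes and the highest other 1, in 1 of 35 splits. At 12, 24 and 48 h the real split called 0 probes, which all 35 splits reach by definition, so the count says nothing about chance there; the highest others were 300, 11 and 1. The 300 and the 11 come from splitting replicates 1 and 2 from 3 and 4, which follows the slides and points to a structure of the samples, and with the slide as a block the real split gave 0. At 6 h the 10 splits are too few for a share under 0.05, with 0 for the real split and 0 for the highest other. For the drug-by-time contrast, with 0 probes too, the 100 of 100 drawn splits say nothing about chance either, with a highest other of 1.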

How the results depend on the processing

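Normexp without negative controls with an offset of 50, leaving out 3 arrays picked by eye from the principal components, median centring over detected probes, only slides 1 and 2, and the slide as a block for lists were tests chosen after the data were seen. Among 997 values of named genes and 124 list calls, no call reversed its direction under any alternative run. A value called neither with the main settings nor with the alternative was counted as unchanged whatever its sign. Detection on all 42 arrays covered 785 of the values. The cause of the moves below was not tested. Most probes lie near background, which limits small changes of dim genes. In the comparisons whose same-numbered arrays all correlated above 0.1, the replicate block changed no call of a named gene or list, while the counts for 48 h against 6 h went to 5955 for AZD1152 and 6695 for SNS-314.

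With median centring AZD1152 called 61, 30, 756, 887 and 2957 probes at 6, 12, 18, 24 and 48 h and SNS-314 called 65, 56, 181, 492 and 3245; the drugs differed in 1 probe at 18 h, and 48 h differed from 6 h in 2160 probes for AZD1152 and 2784 for SNS-314. The share of higher probes was then 20%, 93.8%, 93.3% and 82.5% for AZD1152 from 12 h (34.4%, 50.7%, 48.2% and 50.7% before) and 41.5%, 60.7%, 89.5%, 83.1% and 82.1% for SNS-314 from 6 h (52.8%, 40.8%, 48.5%, 48.4% and 51.9%), and 60.8% and 70.7% for 48 h against 6 h (50.5% and 51.1%). The median change of all tested probes was 0.15, 0.14, 0.26, 0.28 and 0.20 for AZD1152, 0.20, 0.25, 0.20 and 0.20 for SNS-314 from 12 h and 0.13 for SNS-314 at 48 h against 6 h. Centring over detected probes moved it the other way, to −0.13, −0.13 and −0.12 for AZD1152 and −0.11, −0.11 and −0.13 for SNS-314 at 18, 24 and 48 h. The share of higher probes from 12 h was then 21.9%, 28.5%, 26.1% and 38.2% for AZD1152. For SNS-314 it was 24.6%, 28.8%, 31.7% and 37.7%.

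Array weights gave 469, 632 and 1119 probes for AZD1152 at 6, 12 and 18 h, 1404 for SNS-314 at 12 h and 3 between the drugs at 18 h. Without the 3 arrays AZD1152 called 742 at 18 h and the drugs differed in 0. Only slides 1 and 2 gave 187 for AZD1152 at 12 h, 246 and 548 for SNS-314 at 12 and 18 h and 3 between the drugs at 18 h. Only the arrays compared gave 153, 217 and 454 for AZD1152 at 6, 12 and 18 h, 198 and 170 for SNS-314 at 6 and 12 h, 0 between the drugs at 18 h and 2 for the drug-by-time contrast. The replicate block gave 674 for AZD1152 and 844 for SNS-314 at 12 h and 12 between the drugs at 18 h; the slide block gave 846 for SNS-314 at 12 h and 15 between the drugs, and probes detected on all 42 arrays gave 9. With the controls split 2 and 2, probes called the same way under both drugs numbered 110 to 118, 92 to 104, 261 to 307, 608 to 645 and 2802 to 2946 at 6, 12, 18, 24 and 48 h, against 227, 265, 777, 1449 and 4590.

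Leaving out 1 array gave 168 to 272, 266 to 340, 1095 to 2516, 1451 to 1816 and 4718 to 5128 probes for AZD1152 at the 5 times, 255 to 357, 311 to 681, 632 to 961, 1676 to 2160 and 5164 to 5669 for SNS-314, 3 to 76 and 0 to 1 between the drugs at 18 and 24 h, 4264 to 4862 and 4782 to 5540 for 48 h against 6 h, and 0 to 1 for the drug-by-time contrast. Counts moved over 1.5-fold for AZD1152 at 6 h without replicate 2 (184) or 3 (168), at 12 h without replicate 3 (278) or 4 (266) or control replicate 3 (269) and at 18 h without replicate 1 (1095), and for SNS-314 at 6 h without replicate 2 (255) or control replicate 3 (276), at 12 h without replicate 3 (358) or 4 (311) or control replicate 3 (349) or 4 (345) and at 18 h without control replicate 3 (632). Between the drugs at 18 h they were 3, 13, 76 and 3 without AZD1152 replicates 1 to 4 and 8, 3 and 9 without SNS-314 replicates 1, 3 and 4, at 24 h 1 without AZD1152 replicate 3, and for the drug-by-time contrast 1 without AZD1152 6 h replicate 2.

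Of the 124 list calls, 102 passed with an estimated correlation, 121 with fry, 114 with the largest-variance probe, 111 with median centring, 122 with the slide block, 123 with the replicate block and 124 with no background correction or with the authors' values. Of the 997 values of named genes, calls were lost in 308 with median centring, 78 with centring over detected probes, 128 with only slides 1 and 2, 128 with only the arrays compared, 67 with no filter, 37 without the 3 arrays, 33 with looser detection, 19 with the slide block, 16 with array weights, 10 with no background correction, 10 with the authors' values, 5 with an offset of 50, 4 with trend and robust variances and 1 with the replicate block. Leaving out single arrays lost 606 of 7642. The 997 and the 7642 also hold values not called with the main settings, which could not lose a call. The share of calls lost is therefore larger than these totals give.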

Other observations

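YAP target genes, which respond to cell shape and contact, rose as a list at 6 h, with a median of 0.22 for AZD1152 and 0.25 for SNS-314 (13 genes; adjusted p = 0.00134 and 0.0012), 0.25 each with the slide as a block; 2 members rose with each drug (2 and 3 adjusted over the list alone), among them CCN1, a matrix-associated signalling gene (0.87 ± 0.19 and 0.83 ± 0.19, the SNS-314 call ending without SNS-314 replicate 1, at 0.77, and both calls with median centring, at 1.07 and 0.98). At 48 h the list's median was −0.02 and −0.06 (adjusted p = 0.734 and 0.588). Hypoxia and glycolysis genes rose as a list of 25 at 24 h, with 5 and 6 members higher (6 and 8 adjusted over the list alone; median 0.07 and 0.02, adjusted p = 0.0103 and 0.0178), among them the glucose transporter gene SLC2A3 (0.90 and 0.94); at 48 h the median was 0.08 and 0.05 (adjusted p = 0.223 and 0.168). Slides 1 and 2 gave YAP medians of 0.14 and 0.36 for AZD1152 and 0.18 and 0.42 for SNS-314 at 6 h.

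Other lists went both ways at 48 h. Of 22 immediate-early and MAPK output genes 7 rose with each drug and 2 and 3 fell (median 0.14 and 0.12, adjusted p = 0.13 and 0.237), with the transcription factor genes KLF4 at 1.30 and FOSB at 1.02 with AZD1152. Of 20 extracellular matrix genes 6 and 3 rose and 3 fell with each drug (median 0.16 each, adjusted p = 0.371 and 0.37), with the laminin gene LAMA4 at 0.71 and the matrix gene THBS1 at −0.82 with AZD1152. Of 10 BCL2 family genes, which govern cell death, 3 and 4 rose and 2 fell (median 0.17 and 0.20, adjusted p = 0.645 and 0.389), with the pro-death gene BBC3 at 0.61 and the survival gene BCL2 at −0.53 with AZD1152, the BCL2 call ending with median centring (−0.21). Limma called 0 of 3 keratinocyte markers (median 0.21 and 0.18, adjusted p = 0.398 and 0.479) and 0 of 5 immune cell markers (median −0.13 and −0.15, adjusted p = 0.862 and 0.773) with either drug; at an unadjusted p under 0.05 there were 1 and 1, and 0 and 1.

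All tests of the following hypothesis were chosen after the result was seen. The replication genes may fall before the mitotic genes do. The mean of the replication list minus that of the mitotic list was lower at 12 h than in the control by −0.50 for AZD1152 (−0.81 ± 0.10 against −0.31 ± 0.07, SD, n = 4 each) and by −0.53 for SNS-314 (−0.84 ± 0.13). Within slides 1 and 2 the differences were −0.44 and −0.53 for AZD1152 and −0.50 and −0.39 for SNS-314. These values restate, on the same arrays, the moves of the lists that prompted the hypothesis, so they do not decide it. The drugs share the 4 control arrays, and no untreated cells were measured at 12 h, so a shift in the cycle with time in culture stays open.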
